A study of Mus musculus with 9 samples.

How the data were processed

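Primary mouse tracheal epithelial cells in air-liquid interface culture were measured at days 0, 2 and 7 on 2-colour MEEBO arrays, a set of long oligonucleotide probes for mouse transcripts. Per the labels, total RNA was reverse transcribed from oligo-dT primers and each extract was split and labelled with Cy3 and with Cy5 through dye-bearing dendrimers. The labels give 3 replicates of each day, so 9 extracts were hybridised to 9 arrays. The arrays of each replicate number formed a loop of 3, with day 0 in Cy3 and day 2 in Cy5, day 2 in Cy3 and day 7 in Cy5, and day 7 in Cy3 and day 0 in Cy5. The 2 channels that hold the same extract were treated as technical, and the replicate loop (n = 3) was the unit of replication. The labels do not say whether the numbered replicates came from separate animals or cultures.

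The deposited scanner files hold the foreground and local background intensity of each of 38976 spots in both channels, with no normalization applied to the columns used here. Per the file headers they were written by ScanArray Express 2.00 with adaptive circle quantitation, with laser powers of 90 and 90 and photomultiplier settings of 68 and 57 for Cy3 and Cy5 on all 9 arrays. The percent of saturated pixels per spot is also given in these deposited files. Each array also has a deposited scan marked as low, and those 9 files carry no header, so that their settings are not given in the sources used here. The headers also name a lowess normalization, whose columns were not used. The deposited value table of the series holds log2 ratios of Cy5 over Cy3, made with limma per the submitters' processing notes, with version and settings not given in the sources used here. Its base and direction were found by setting each column against the scanner log ratios of the same array across genes, which gave correlations of 0.94 to 0.984 and slopes of 0.837 to 0.938. Its column medians lay between -0.0169 and 0.000829, and how the authors centred it and whether they scaled it stayed unknown. It served as an alternative.

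Of the 38976 spots, 3898 were controls or empty and 35078 were probes for mouse transcripts. Probe names of 1 form appeared to hold an NCBI gene number, and these were looked up in a RefSeq gene table (assembly GRCm38.p6, used for names alone). Of 12225 such probes, 82.75% matched a gene, against 26.83% for random numbers nearby, and at most 7.64% of the named probes could be chance matches. Pairs of probes given the same gene correlated at 0.693 in their change from day 0 to day 7 over 1164 pairs, and random pairs at -0.0138. In this way 10116 probes were given a single gene symbol (8241 genes), none several, and 24962 were not named here.

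Background was corrected with normexp (offset 50) on mean foreground and median background, and log ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control and empty spots were then left out, and saturated spots were kept. A probe was kept where its foreground exceeded the background median by 2 background SD in at least 3 of the 6 channels of any 1 day. For each named gene the probe with the highest mean brightness was used, and 1595 genes had over 1 probe. Spots were not removed by the scanner's flag codes, although this had been planned, because the files do not explain the codes. On each array, 43.2 to 62.23% of transcript probes lay above background in Cy3 and 56.17 to 76.87% in Cy5. Spots of random sequence passed the same test in 5.155 to 24.74% and 17.53 to 51.55% of cases, and empty spots in 0.5894 to 1.768% and 0.5894 to 2.554%. The number of arrays limits the precision.

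Log2 ratios of all 9 arrays were fitted with limma (lmFit and eBayes) to the differences between days and a dye term for each loop and gene, which left 4 residual degrees of freedom, with 4.33 more from the prior. Each fitted change equals the mean of the 3 loops' values, given here with their SD. P-values were adjusted by the Benjamini-Hochberg method over 23538 genes, and genes with an adjusted p under 0.05 were called. A moderated F test over both day differences gave the genes changed across the 3 days. The dye terms of the loops correlated at 0.819 to 0.892 across genes. Pairing was built in by hybridising same-numbered extracts together, and in separate channels the deviations of same-numbered extracts from their day means correlated at 0.187 to 0.568 in the 3 loops. Any 2 same-numbered extracts share an array, whose spot effects alone can give such correlations, so these do not show that the extracts are related. Loop 1 was quantified on 1 date and loops 2 and 3 on another, so that date did not differ between days within a loop. No 2 arrays of a day pair correlated above 0.855.

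Before the data were examined, 29 gene lists and the rule for the genes named in the text were fixed, as were the comparisons and the alternatives apart from a filter on random-sequence spots. The rule takes for each comparison the 10 highest and 10 lowest log2 changes among called genes with the same direction in 3 loops, leaving out clone and provisional names and genes not above background on either day, with up to 4 members of each list with the smallest p, and 8 markers whatever their values. For 7 of these 8 (Foxj1, Myb, Mcidas, Krt5, Krt14, Trp63 and Scgb1a1) no probe was named here. Outside this rule, Cd44, Clca1, Dnah5, Dst, Eno1, Gclm, Hydin, Krt8, Krt15, Krt18, Krt19, Ldha, Muc4, Pgk1, Pigr and Slc4a4 were named in at least 1 comparison after their values were seen. Lists were tested with camera (preset correlation 0.01) and adjusted over the 72 tests of 24 lists and 3 comparisons, with camera at an estimated correlation and fry beside it. With an estimated correlation camera takes its p from the 4 residual degrees of freedom, not from the number of genes. Its p is then larger even where the correlation is small. The 5 lists with under 3 genes tested (chondrocyte, erythroid, ionocyte, smooth muscle, and thyroid and muscle) were not tested. Only members with a named probe that passed the filter were tested, so each list was tested in part. Tested were 18 of 87 motile axoneme, 22 of 54 proliferation, 11 of 30 basal cell, 8 of 45 matrix and migration and 5 of 16 multiciliated transcription members. Where a gene was not well above background, or was saturated, in all 6 channels of a day, its fold is a bound from means of normalized log2 intensities per channel after loess and Aquantile. In it a value is set no lower than the dimmest transcript probe above background in that channel. Such a bound leaves out the spread between loops, so it is a bound on the means alone.

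The fit was tested on simulated log ratios of the 23538 genes with 200 seeded changes. For day 2 against day 0 it recovered 2.99% of 1.5-fold, 49.3% of 2-fold and 100% of 4-fold changes, with 6 unchanged genes called. For day 7 against day 0 the shares were 10.4%, 55.2% and 95.5% with 11 unchanged genes called. For day 7 against day 2 they were 2.99%, 50.7% and 95.5% with 6, and for the F test 4.48%, 58.2% and 95.5% with 7. With no change simulated, calls numbered 0, 1, 0 and 0. In the simulation of day 7 against day 0, camera called the 1 changed list and 0 of 20 unchanged lists. Its noise was independent between genes, so it does not test camera on lists whose genes vary together. The real lists had estimated correlations of up to 0.503. The alternatives varied the scan, background correction, foreground, normalization, filter, probe choice, dye term, pairing, variance model, array weights, values and replicates. Figures were drawn with matplotlib 3.10.9.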

Results

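Primary mouse tracheal epithelial cells were profiled as they differentiated at an air-liquid interface, a culture in which cells on a porous membrane are fed from below and exposed to air above. The labels give cells of male C57BL/6J mice at days 0, 2 and 7 after air exposure, with 3 replicates of each day. Each replicate's 3 extracts were compared with each other in a loop of 3 arrays. Because the labels do not say whether replicates came from separate mice or cultures, p-values measure the spread between these extracts, which may be technical. Median foreground intensity of the transcript probes was 402 to 613 in Cy3 and 300 to 532 in Cy5, over median backgrounds of 168 to 218 and 132 to 142. In all, 23538 genes were tested, 6635 of them with a gene symbol. Across the 3 days 3285 genes changed (limma F test, adjusted p under 0.05), 911 of them named. Changes are log2 differences between days, as the mean ± SD of 3 replicate loops, and p-values are limma's, adjusted by the Benjamini-Hochberg method.

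The first comparison, of day 2 with day 0, asked what the first days in air changed. Some genes of detoxification and motile cilia rose, while some of glycolysis and the hypoxia response, cell division, basal cells, squamous differentiation and matrix fell. Of 16 secretory genes 5 rose and 5 fell. None of the lists behind this was called with an estimated correlation (lowest adjusted p = 0.0799), and members that did not pass are counted with each list. Counts here and below are of the tested members, which were a part of each list, such as 18 of 87 for motile axoneme. Cyp2a5, a cytochrome P450 that hydroxylates coumarin, rose by 4.33 ± 0.44 (SD, n = 3; adjusted p = 0.0001135), and its relatives Cyp2a12 and Cyp2a4 rose by 4.67 ± 0.28 and 4.49 ± 0.42 (SD, n = 3). At the other end Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor and is itself induced by hypoxia, fell by 3.95 ± 0.34 (SD, n = 3; adjusted p = 0.0001447). In all 1509 genes changed, 685 higher and 824 lower at day 2, and 990 of them by at least 2-fold. Each of the 1509 had the same direction in all 3 loops. Some named genes were near background on their dimmer day, so the sizes of their changes are uncertain. Of its 6 channels, day 0 had 2 above background for Dnali1, 3 for Dnah5 and 4 for Cyp2a12, Cyp4a12b and Clca1. Day 2 had 2 for Igfbp4 and Srd5a1, 3 for Kif3c and 4 for Cd44, Myl7, Spp1 and Krt20.

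Of 16 tested genes of hypoxia and glycolysis, 12 fell and 4 did not pass, and the count was again 12 adjusted over the list alone. The list's median was -1.17 (camera adjusted p = 1.81e-13, and adjusted p = 0.0799 with an estimated correlation). Beside Egln3, the endoplasmic oxidase gene Ero1a fell by 2.74 ± 0.41 (SD, n = 3). The changes of the glycolytic enzyme genes Pgk1, Pfkl and Eno1 were -2.09 ± 0.47, -1.38 ± 0.10 and -1.71 ± 0.52 (SD, n = 3). Ldha, which makes lactate from pyruvate, was saturated at day 0 and at least 2.13-fold lower at day 2 (adjusted p = 0.004989).

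Of 17 detoxification and oxidation genes, 9 rose and 8 did not pass, with 10 higher adjusted over the list alone (median 0.959, camera adjusted p = 1.92e-09, and adjusted p = 0.253 with an estimated correlation). Cyp4a12a, a fatty acid hydroxylase, rose by 2.44 ± 0.35 (SD, n = 3). The glutathione transferase genes Gsta1 and Gsta2 rose by 2.14 ± 0.49 and 2.05 ± 0.49 (SD, n = 3), and Gclm, a subunit of the enzyme that makes glutathione's precursor, by 1.62 ± 0.53 (SD, n = 3). Club and secretory genes went both ways, with 5 of 16 higher, 5 lower and 6 not passed, and 6 higher and 5 lower adjusted over the list alone (median 0.291, camera adjusted p = 0.383). Aldh1a1, which makes retinoic acid, rose by 3.21 ± 0.62 (SD, n = 3), the mucus-associated Clca1 by 1.74 ± 0.78 (SD, n = 3) and ceruloplasmin, Cp, by 1.11 ± 0.24 (SD, n = 3). Pigr, the receptor that carries antibodies into the airway, fell (adjusted p = 0.004367), and the mucin gene Muc4 and the keratin genes Krt8, Krt18 and Krt19 fell too.

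Of 18 motile axoneme genes, 8 rose and 10 did not pass, with 10 higher adjusted over the list alone (median 0.761, camera adjusted p = 5.33e-09, and adjusted p = 0.253 with an estimated correlation). The inner dynein arm gene Dnali1 rose by 2.06 ± 0.14 and Nme5 by 1.97 ± 0.24 (SD, n = 3), while Dnah5, an outer dynein arm heavy chain, was 0.81 ± 0.16 higher (SD, n = 3) and did not pass (adjusted p = 0.06959). Of 12 centriole amplification genes 5 rose and 7 did not pass, with 6 higher adjusted over the list alone (median 0.575, camera adjusted p = 0.000125, and adjusted p = 0.537 with an estimated correlation), among them Ccp110 by 1.59 ± 0.89 (SD, n = 3) and Pcm1 by 1.09 ± 0.29 (SD, n = 3). Among 12 genes of intraflagellar transport, the traffic along the cilium, Ift57 and Arl6 rose, Kif3c fell and 9 did not pass. The counts adjusted over the list alone were 5 higher and 1 lower (camera adjusted p = 0.0696). The transcription factor gene Rfx2, which drives cilium genes, rose by 1.28 ± 0.74 (SD, n = 3), and the other 4 tested members of its list did not pass (camera adjusted p = 0.298).

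Of 22 proliferation genes, 10 fell and 12 did not pass, with 11 lower adjusted over the list alone (median -0.854, camera adjusted p = 6.56e-09, and adjusted p = 0.253 with an estimated correlation). Ube2c, which acts with the anaphase-promoting complex, and Mki67, a marker of cycling cells, changed by -1.85 ± 0.51 and -1.58 ± 0.37 (SD, n = 3). Of 11 basal cell genes 7 fell and 4 did not pass, with 9 lower and 1 higher adjusted over the list alone (median -1.22, camera adjusted p = 4.99e-07, and adjusted p = 0.253 with an estimated correlation). They included Cd44 at -1.82 ± 0.79 (a dimmer second probe gave -0.215), Itga6 at -1.31 ± 0.24 and the placental cadherin gene Cdh3 at -1.22 ± 0.21 (SD, n = 3). Of 21 squamous and cornified genes 6 fell and 15 did not pass, with 7 lower adjusted over the list alone (median -0.566, camera adjusted p = 4.32e-05, and adjusted p = 0.253 with an estimated correlation), among them the stress keratin gene Krt6a at -2.51 ± 0.22 (SD, n = 3) and the desmosome gene Dsc2 at -1.83 ± 0.21 (SD, n = 3). Of 8 matrix and migration genes 6 fell, also adjusted over the list alone (median -1.24, camera adjusted p = 1.33e-06, and adjusted p = 0.14 with an estimated correlation), such as Thbs1 at -1.64 ± 0.17 (SD, n = 3) and Col7a1, the anchoring fibril collagen (adjusted p = 0.00474). Of 16 cholesterol synthesis genes, Tm7sf2 fell and 15 did not pass, with 5 lower and 1 higher adjusted over the list alone (median -0.505, camera adjusted p = 0.000968, and adjusted p = 0.619 with an estimated correlation).

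Other large rises were those of the lysozyme genes Lyz2 and Lyz1, by 3.71 ± 0.83 and 2.74 ± 0.14 (SD, n = 3). Cyp4a12b and the carboxylesterase gene Ces1c rose by 2.83 ± 0.90 and 2.43 ± 0.96 (SD, n = 3). Other large falls were those of the growth factor binding protein genes Igfbp3 and Igfbp4 at -3.35 ± 0.91 and -2.69 ± 0.92 (SD, n = 3), Myl7 at -3.12 ± 0.46 (SD, n = 3), osteopontin, Spp1, at -2.93 ± 1.16 (SD, n = 3) and Krt20 at -2.86 ± 0.36 (SD, n = 3). Srd5a1, Ass1 and Gdf11 changed by -2.78 ± 0.63, -2.66 ± 0.90 and -2.54 ± 1.12 (SD, n = 3). The probes of close relatives (Cyp2a4, Cyp2a5 and Cyp2a12, Cyp4a12a and Cyp4a12b, Lyz1 and Lyz2, Gsta1 and Gsta2, Krt6a and Krt6b) may not separate them. Gsta1 and Gsta2 were still counted as separate genes of the detoxification list, and Krt6a and Krt6b of the squamous list. So were Ugt1a1 and Ugt1a6a, of the detoxification list, whose transcripts share their last exons. The counts and camera p-values of both lists may therefore rest on fewer separate changes, in each comparison. A dimmer second probe of Cyp2a12 gave -0.0423 at day 2 and 0.836 at day 7. Dimmer probes departed from those used also at day 2 for Ces1c (0.0497), Mki67 (-0.521), Lyz1 (1.77) and Lyz2 (2.47), and of the other 2 probes of Ero1a, 1 gave -0.267 and 1 gave -2.96. The count of 1509 was 933 without replicate 1, which leaves the loops of a single quantitation date, 393 without replicate 2, 397 without replicate 3 and 515 in separate channels with no replicate block.

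**Figure D1:**
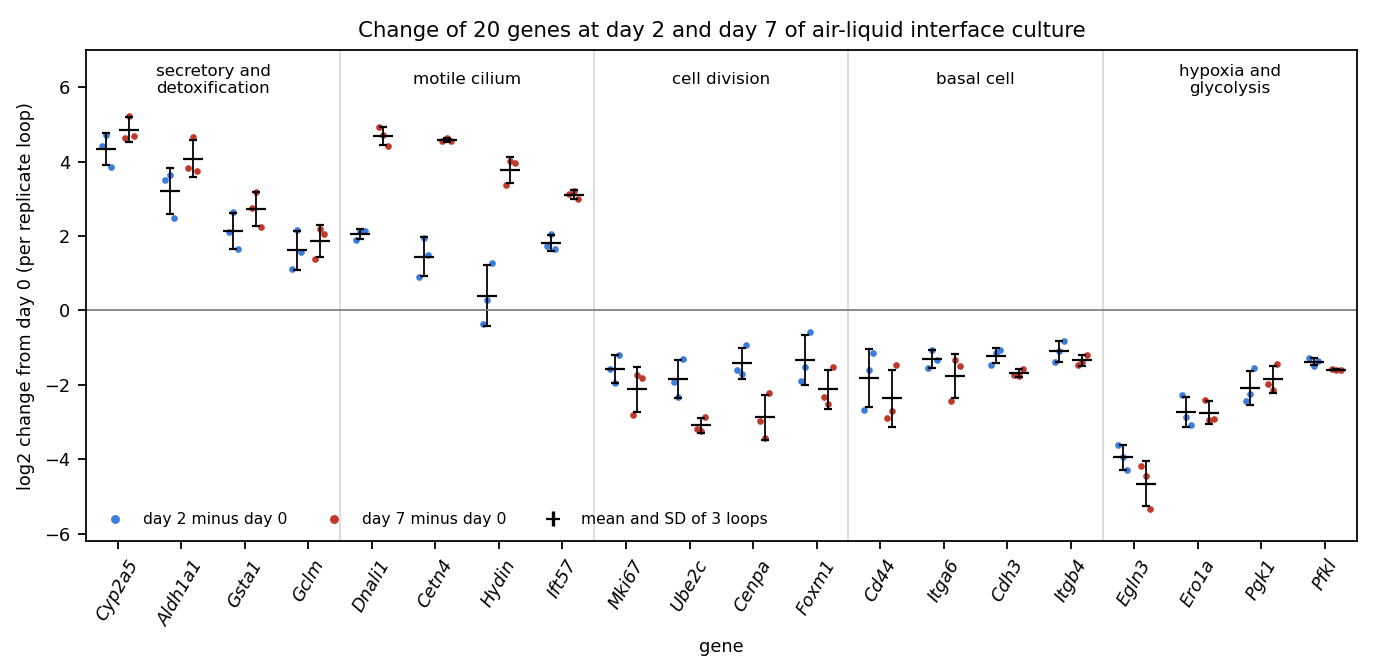
Log2 change from day 0 (vertical axis) of 20 genes in 5 groups at day 2 (blue) and day 7 (red). Each point is 1 of 3 replicate loops, with black bars for their mean and SD. Cyp2a5 and Aldh1a1 at day 7 were saturated, so that their day 7 points understate the change. Dnali1 and Hydin were above background in 2 of 6 channels at day 0. Genes of the secretory list that fell, such as Pigr and Muc4, are not drawn. Egln3 changed by -3.95 at day 2 and -4.67 at day 7.

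The second comparison, of day 7 with day 0, asked how the differentiated culture differed from its start. Of the lists, motile axoneme genes had the highest median, 12 of 17 detoxification genes were higher than at day 0, and 18 of 22 cell division, 9 of 11 basal cell and 12 of 16 hypoxia and glycolysis genes were lower. None of these lists was called with an estimated correlation (lowest adjusted p = 0.0799). Dnali1 rose by 4.69 ± 0.25 (SD, n = 3; adjusted p = 3.611e-06), and the centrin gene Cetn4 by 4.58 ± 0.05 (SD, n = 3). Egln3 and Ube2c changed by -4.67 ± 0.60 and -3.09 ± 0.21 (SD, n = 3; adjusted p = 9.092e-06 and 3.399e-05). In all 3878 genes changed, 2221 higher and 1657 lower at day 7, and 2186 of them by at least 2-fold. Of its 6 channels, day 0 had 2 above background for Dnali1 and Hydin, 3 for Dnah5, Saxo2, Agr3 and Slc5a8, and 4 for Cyp2a12, Cetn4 and Slc26a9. Day 7 had 2 for Slc26a9, 3 for Cd44 and 4 for Tk1 and Myl7. For these genes, near background on 1 day, the sizes of the changes are uncertain.

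Of 18 motile axoneme genes, 15 rose and 3 did not pass, with 16 higher adjusted over the list alone (median 3.08, camera adjusted p = 6.16e-16, and adjusted p = 0.145 with an estimated correlation). Nme5 rose by 4.12 ± 0.23, Hydin, a protein of the central pair, by 3.78 ± 0.36 and Dnah5 by 3.20 ± 0.56 (SD, n = 3). Hydin and Dnah5 were near background at day 0, so the sizes of their rises are uncertain. Outside that list Saxo2, a microtubule protein of axonemes, and Agr3, a disulfide isomerase, rose by 4.68 ± 0.38 and 4.19 ± 0.40 (SD, n = 3). Of 12 intraflagellar transport genes 5 rose and 7 did not pass, with 6 higher and 1 lower adjusted over the list alone (median 0.481, camera adjusted p = 0.00117, and adjusted p = 0.253 with an estimated correlation), led by Ift57 at 3.12 ± 0.11 (SD, n = 3). Of 12 centriole amplification genes 7 rose and 5 did not pass, with 8 higher adjusted over the list alone (median 0.882, camera adjusted p = 0.000125, and adjusted p = 0.537 with an estimated correlation), with Ccp110 at 2.25 ± 0.47 and Poc5 at 1.58 ± 0.22 (SD, n = 3). Rfx2 rose by 2.17 ± 0.44 (SD, n = 3), again alone among the 5 tested genes of multiciliated transcription (camera adjusted p = 0.389).

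Of 17 detoxification and oxidation genes 12 rose, also adjusted over the list alone, and 5 did not pass (median 1.28, camera adjusted p = 1.3e-07, and adjusted p = 0.253 with an estimated correlation), with Cyp4a12a at 2.98 ± 0.34 and Gsta1 at 2.73 ± 0.47 (SD, n = 3). Club and secretory genes were again split, 5 higher, 5 lower and 6 not passed, with 6 higher and 5 lower adjusted over the list alone (median 0.316, camera adjusted p = 0.438). Cyp2a5 and Aldh1a1 were saturated at day 7. Cyp2a5 rose (adjusted p = 5.003e-06), by an amount not given here, and Aldh1a1 rose at least 14.3-fold (adjusted p = 2.755e-05). Cyp2b10 rose by 2.63 ± 0.43 (SD, n = 3), and Muc4 and Pigr changed by -1.42 ± 0.16 and -1.45 ± 0.46 (SD, n = 3). Cyp2a12 and Cyp2a4 rose by 6.23 ± 0.47 and 5.54 ± 0.56 (SD, n = 3).

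Of 22 proliferation genes 18 fell and 4 did not pass, with 19 lower adjusted over the list alone (median -1.28, camera adjusted p = 8.12e-12, and adjusted p = 0.253 with an estimated correlation). The changes of thymidine kinase, Tk1, the centromere histone gene Cenpa and Mki67 were -3.01 ± 1.15, -2.87 ± 0.61 and -2.12 ± 0.60 (SD, n = 3), while dimmer second probes of Tk1 and Mki67 gave -1.73 and -1.1. Of 11 basal cell genes 9 fell, also adjusted over the list alone (median -1.55, camera adjusted p = 1.96e-06, and adjusted p = 0.255 with an estimated correlation). Cd44 and Itga6 changed by -2.36 ± 0.77 and -1.76 ± 0.59 (SD, n = 3), although the second probe of Cd44 gave -0.00936, while Krt15 and Dst were at 0.19 ± 0.18 and 0.13 ± 0.27 (SD, n = 3) and did not pass. Of 21 squamous and cornified genes 6 fell and 15 did not pass, with 7 lower adjusted over the list alone (median -0.464, camera adjusted p = 0.000383, and adjusted p = 0.253 with an estimated correlation), with Dsc2 at -2.36 ± 0.27 (SD, n = 3). Of 8 matrix and migration genes 6 fell, or 7 adjusted over the list alone (median -1.1, camera adjusted p = 1.76e-05, and adjusted p = 0.145 with an estimated correlation), with Ccn1, a matrix-associated signalling protein, at -2.58 ± 0.14 (SD, n = 3).

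Of 16 hypoxia and glycolysis genes 12 fell, also adjusted over the list alone, and 4 did not pass (median -1.46, camera adjusted p = 1.15e-09, and adjusted p = 0.0799 with an estimated correlation). Ero1a, Pgk1 and Pfkl changed by -2.75 ± 0.30, -1.86 ± 0.37 and -1.59 ± 0.01 (SD, n = 3), with 0.0713 and -3.19 from the other probes of Ero1a, and Ldha, saturated at day 0, was at least 2.89-fold lower (adjusted p = 0.0003533). Of 16 cholesterol synthesis genes Abcg1 rose, Acat2 and Lss fell and 13 did not pass, with 1 higher and 4 lower adjusted over the list alone (median -0.563, camera adjusted p = 0.00254, and adjusted p = 0.643 with an estimated correlation), and the list missed the threshold without replicate 1 (camera adjusted p = 0.0804). Abcg1, a sterol exporter that was not well above background at day 0, rose at least 1.77-fold by its means, a bound that leaves out the spread between loops. Among 14 ion and fluid transport genes Clic6 and Slc5a8 rose by 1.29 ± 0.13 and 1.71 ± 0.61 (SD, n = 3), with 0.916 from a dimmer second probe of Slc5a8. In that list the water channel gene Aqp4, the anion transporter gene Slc26a9 and Slc4a4 changed by -1.59 ± 0.53, -1.20 ± 0.28 and -0.54 ± 0.05 (SD, n = 3), and 9 did not pass (3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.915). Intu, a planar polarity effector needed for cilia, rose by 1.30 ± 0.06 (SD, n = 3), and the other 10 planar polarity genes did not pass (camera adjusted p = 0.901).

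Further large falls at day 7 were those of Myl7 at -3.40 ± 0.52, Igfbp3 at -3.31 ± 0.46, Spp1 at -3.11 ± 1.35 and the mediator subunit gene Med24 at -3.06 ± 0.43 (SD, n = 3). Igfbp4, not well above background at day 7, fell (adjusted p = 0.0004427), at least 8.94-fold by its means, a bound that leaves out the spread between loops. Lyz2 and Lyz1 rose by 4.43 ± 0.31 and 4.29 ± 0.75 (SD, n = 3), and a dimmer second probe of Lyz1 gave 2.45. The count of 3878 was 2954 without replicate 1, 1857 without replicate 2, 1827 without replicate 3 and 1914 in separate channels with no replicate block.

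**Figure D2:**
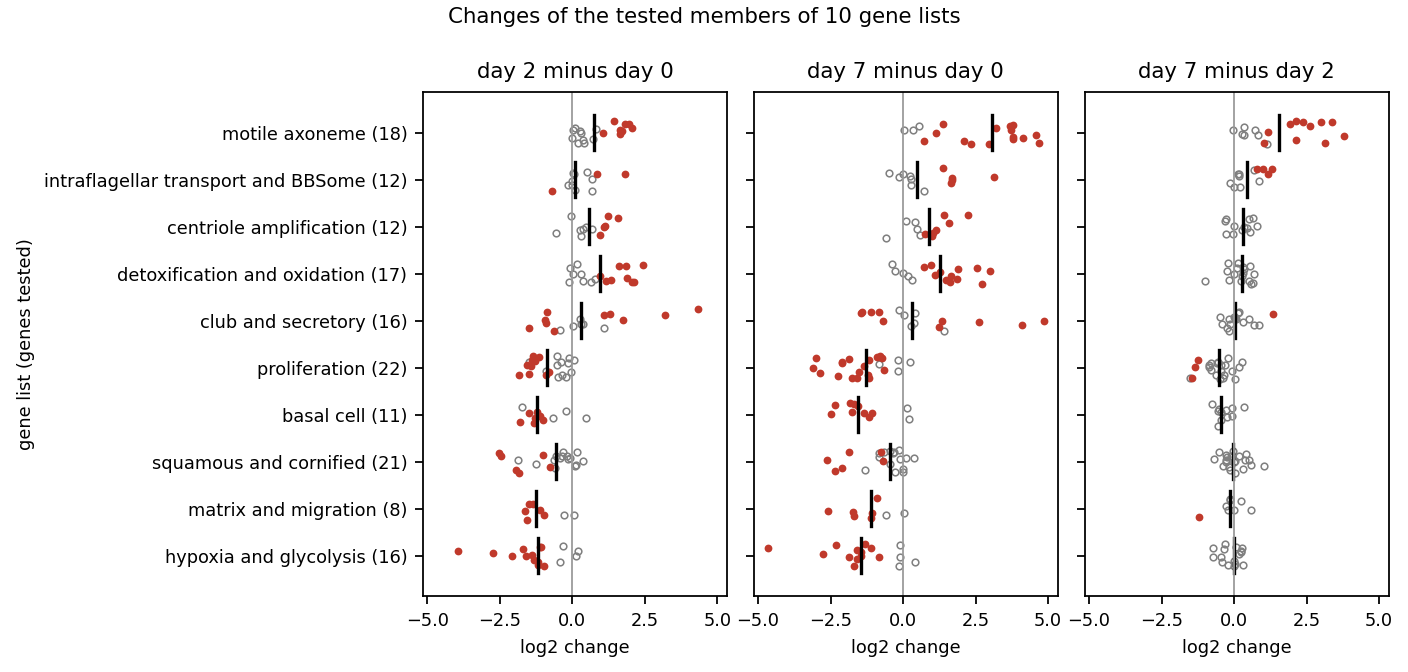
Log2 change (horizontal axis) of each tested gene of 10 lists in the 3 comparisons. Filled red points passed the adjusted p threshold, open points did not, and black bars are list medians. The motile axoneme median was 0.761, 3.08 and 1.56 in the panels from left to right, and that of hypoxia and glycolysis -1.17, -1.46 and -0.00684.

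The third comparison, of day 7 with day 2, asked what changed after the first 2 days. Of the motile axoneme genes 11 of 18 rose, 3 of 22 cell division genes fell, neither list was called with an estimated correlation (adjusted p = 0.145 and 0.255), and no gene of the glycolysis or basal cell lists passed. Cdhr4, a cadherin-related protein, rose by 3.81 ± 0.14 (SD, n = 3; adjusted p = 7.238e-05). Hydin rose by 3.38 ± 0.60 and the tubulin gene Tuba1a by 3.00 ± 0.34 (SD, n = 3). In all 907 genes changed, 808 higher and 99 lower at day 7, and 671 of them by at least 2-fold. With all changes shifted down by 0.19, at most 60% of calls would be higher, and no alternative varied the centre. Of its 6 channels, day 2 had 1 above background for Cfap97d2 and Cdh26, 2 for Cdhr4, 3 for Vwa3a and 4 for Hydin and Kcnrg, and day 7 had 4 for Nusap1. The sizes of changes so near background are uncertain.

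Of 18 motile axoneme genes 11 rose and 7 did not pass, with 14 higher adjusted over the list alone (median 1.56, camera adjusted p = 1.97e-17, and adjusted p = 0.145 with an estimated correlation), and Dnali1 and Dnah5 rose by 2.63 ± 0.38 and 2.39 ± 0.42 (SD, n = 3). Of 12 intraflagellar transport genes 4 rose and 8 did not pass, with 6 higher adjusted over the list alone (median 0.457, camera adjusted p = 0.000125, and adjusted p = 0.253 with an estimated correlation). They were Ift57 at 1.30 ± 0.13, the kinesin motor gene Kif3a at 1.17 ± 0.24, Ttc26 at 0.99 ± 0.45 and Arl6 at 0.81 ± 0.28 (SD, n = 3). In the centriole amplification list limma called 0 of 12, and 3 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.252). Other large rises were those of Cfap97d2 by 3.66 ± 0.58, Kcnrg by 3.33 ± 0.47, Vwa3a by 3.32 ± 0.32 and Cetn4 by 3.14 ± 0.49 (SD, n = 3). Tm4sf1, a tetraspanin-like membrane protein, rose by 3.20 ± 0.59, the cadherin gene Cdh26 by 3.06 ± 0.35 and Saxo2 by 2.99 ± 0.69 (SD, n = 3). Cfap97d2 and Cdh26 were near background at day 2, as counted above, so the sizes of their rises are uncertain. Clic6 rose by 1.18 ± 0.06, Cyp2b10 by 1.33 ± 0.37 and, in the planar polarity list, Wnt11 by 1.73 ± 0.57 and Intu by 0.82 ± 0.09 (SD, n = 3).

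Of 22 proliferation genes Cenpa, Nusap1 and Ube2c changed by -1.46 ± 0.23, -1.36 ± 0.34 and -1.25 ± 0.32 (SD, n = 3), and 19 did not pass. With the p adjusted over the list alone 9 were lower (median -0.508, camera adjusted p = 8.64e-08, and adjusted p = 0.255 with an estimated correlation). Stathmin, Stmn1, which destabilises microtubules, fell (adjusted p = 0.01558), and Ccn1 and the kinetochore gene Knstrn changed by -1.22 ± 0.35 and -1.11 ± 0.28 (SD, n = 3). The changes of Marcksl1, Med24, Wdr76 and the ribosomal protein gene Rps24 were -1.18 ± 0.52, -1.17 ± 0.20, -1.17 ± 0.27 and -1.08 ± 0.63 (SD, n = 3), although dimmer second probes of Wdr76 and Knstrn gave -0.282 and -0.449. The basal cell list had a lower median (-0.442, camera adjusted p = 0.0159, and adjusted p = 0.643 with an estimated correlation; 0.0713 by camera without replicate 2), yet limma called 0 of its 11 genes, also adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. In the hypoxia and glycolysis list limma called 0 of 16, with 5 lower at an unadjusted p under 0.05 (median -0.00684, mean -0.117, camera adjusted p = 0.338), while fry called the list lower (adjusted p = 0.0128). The detoxification list likewise had 0 of 17 called, with 5 higher and 1 lower at an unadjusted p under 0.05 (median 0.288, camera adjusted p = 0.122). The count of 907 was 500 without replicate 1, 364 without replicate 2, 242 without replicate 3 and 405 in separate channels with no replicate block. It was 1394 with a single dye term and 1790 with array weights, and each of the 10 largest falls missed the threshold without at least 1 replicate.

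The day 2 and day 7 changes from day 0 shared 583 higher and 725 lower genes, with 4 opposite, against 64.6, 58 and 126 expected of independent lists. The changes correlated at 0.778 across genes, which are not independent replicates, and the shared day 0 extracts alone gave 0.501 in 20 simulations with no effect. The covariance was 0.276 against 0.0261 in those simulations. The simulations gave 0 shared calls, and part of the excess may come from the shared extracts.

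Markers of other cell types were measured in the same fits. Of 6 fibroblast genes, decorin, Dcn, rose by 2.15 ± 0.65 at day 2 and 1.58 ± 0.80 at day 7 (SD, n = 3), with 1.19 and 1.42 from a dimmer second probe, and the collagen genes Col1a1, Col1a2, Col3a1, Col5a1 and Col6a1 did not pass on either day (camera adjusted p = 0.929 and 0.74). Of 6 channels, Dcn was above background in 4 at day 0, Col1a2 in 2 and Col3a1 in 4 at day 2, and Col6a1 in 1 at day 2. The fibroblast medians were negative (-0.175 and -0.363, camera down) and the means positive (0.194 and 0.026). Of 8 immune genes Lyz2 rose on both days, Cd68, a macrophage marker, changed by -1.40 ± 0.13 and -0.86 ± 0.35 (SD, n = 3), and 6 did not pass (camera adjusted p = 0.786 and 0.901). Of the endothelial, neuroendocrine and tuft lists, with 4, 5 and 4 genes tested, limma called 0 genes at day 7, with 2, 0 and 0 at an unadjusted p under 0.05 and, for the endothelial list, 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.915 for each). Among 5 stress genes Hspb1, a small heat shock protein, rose by 1.12 ± 0.16 and 1.23 ± 0.22 (SD, n = 3) and Junb changed by -1.27 ± 0.44 and -1.20 ± 0.31 (SD, n = 3) at days 2 and 7 (camera adjusted p = 0.74 and 0.915). At day 7 the Notch modifier gene Lfng rose by 0.80 ± 0.47 (SD, n = 3) and 7 of 8 Notch pathway genes did not pass, with 0 called over the list alone (camera adjusted p = 0.611). Of 8 inflammatory genes the chemokine gene Cxcl3 fell by 2.61 ± 0.71 and Il1a rose by 0.93 ± 0.45 (SD, n = 3) at day 7 (camera adjusted p = 0.45). Il1a was above background in 1 of 6 channels at day 0 and Cxcl3 in 2 at day 7, and Lfng in 4 at day 0. With signals so near background, the sizes of these 3 changes are uncertain. Of 16 interferon response genes and 4 of MHC class II, limma called 0 at day 7, with 2 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.786 and 0.785). Median and mean also differed in sign, with camera on the side of the mean, for the immune list at day 7 (-0.104 and 0.419) and between days 7 and 2 (-0.0151 and 0.0964), planar polarity at day 7 (-0.18 and 0.0503) and ion transport at day 2 (0.014 and -0.101). Camera went with the median for the squamous list between days 7 and 2 (-0.0506 and 0.0188) and the tuft list at day 2 (0.0163 and -0.00333).

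As a sign of RNA quality, control probes tiled along 7 transcripts were compared between their upstream and downstream exons. The change from day 0 differed between the 2 parts by a median of -0.16 at day 2 and 0.0493 at day 7. The differences for Lrp1 and Tln1 were the highest, at 0.659 and 0.454 at day 2 and 0.823 and 0.705 at day 7. Among the other 5 transcripts they lay between -0.272 and -0.0879 at day 2 and between -0.167 and 0.0983 at day 7.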

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

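The comparison of forward with reverse-complement probes was chosen after the values of these probes were seen.

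The arrays carry control probes for viruses, which enter none of the comparisons between days. The 40 probes for murine leukemia and sarcoma viruses had a median log2 brightness of 14.8, and 35 of them (87.5%) were brighter than the brightest of the 97 random-sequence spots, against 10.4% of transcript probes. The reverse-complement probes of the same viruses had a median of 9.74, with 7 of 40 above the brightest random-sequence spot, but levels of different probes do not settle how much of either signal is specific. Probes for mouse mammary tumor virus and the forward probes for other viruses had medians of 7.42 and 7.17, against 7.15 for random-sequence spots, although 5 of the 149 for other viruses passed the brightest of these. The forward median changed by -0.26 from day 0 to day 2 and -0.549 to day 7, and the reverse-complement median by -0.289 and -0.557. Unspecific binding would move both kinds of probe alike, and the changes differed by at most 0.029. Because 11 of the 40 forward probes were saturated in at least 1 channel of every array, which may hide a difference, unspecific binding stays open. Mouse genomes hold inherited copies of such viruses, and whether they gave this signal stays open, since no biological explanation was tested.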

How the results depend on the processing

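A filter on random-sequence spots was chosen after seeing the data, and the other alternatives before. None of the 23 called list tests and 178 called changes of named genes (172 and 173 under 2 stricter filters) turned direction under the alternatives run, and the direction of other called genes was not followed. The count between day 7 and day 2 (907) became 1394 with a single dye term and 1790 with array weights, whose estimate stopped short of its tolerance. With a single dye term the residual also takes in technical spread, so it no longer holds the spread between extracts alone. The cause of the rise with array weights was not tested. With separate channels and no replicate block the counts were 515 (day 2 against day 0), 1914 (day 7 against day 0), 405 (day 7 against day 2) and 1533 (3 days), and with the replicate block they stayed within 1.5 times, at 1007, 2869, 630 and 2321. Leaving out each replicate in turn, with fewer samples, gave 393 to 933, 1827 to 2954, 242 to 500 and 1239 to 2146 genes, 23 to 24 called list tests, and 48 to 51 of the 60 genes at either end still called. Without replicates 1, 2 and 3, 36, 59 and 53 of 178 called changes of named genes missed the threshold, as did cholesterol synthesis at day 7 (replicate 1) and basal cell genes between days 7 and 2 (replicate 2). The basal cell list also missed it with all probes tested separately. With an estimated correlation camera called 0 of the 23 list tests, with 11 at an unadjusted p under 0.05. That loss is not due to correlation between genes alone. Hypoxia and glycolysis at day 2, with an estimated correlation of -0.0412, went from an unadjusted camera p of 7.56e-15 to 0.00113. Fry called 19 of the 23, missing centriole amplification (day 2), cholesterol synthesis (days 2 and 7) and the basal cell list (day 7 against day 2). It called 6 others, which made 25: club and secretory and stress genes (days 2 and 7), intraflagellar transport (day 2) and hypoxia and glycolysis (day 7 against day 2). Under the other scans, background corrections, foregrounds, normalizations and filters, at most 8 of the 178 changes were lost, and with separate channels 46, or 20 with the replicate block. Most of the 178 were chosen for large changes or small p, so they may hold better than other calls. Of all genes called (day 2 against day 0, day 7 against day 0, day 7 against day 2), the low scan kept 1234 of 1509, 3331 of 3878 and 782 of 907. Normexp with offset 0 kept 1205, 3406 and 687. Signal over background limits the dim genes: up to 51.55% of random-sequence spots passed the background test in a channel, and requiring probes brighter than 95% of them gave 1935, 3973, 1123 and 3541 genes. Scaling between arrays by Aquantile leaves log ratios as they are. A block for quantitation date was not run, since it is nested in the loops.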

Other observations

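The tests in this part were chosen after the results were seen, except the relabelling of days.

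Genes were also grouped into families by symbol prefix. Of 87 families with at least 8 tested members, the ribosomal protein prefixes had negative medians between days 2 and 7, with few genes called. The 41 Rpl genes had a median of -0.244 from day 2 to day 7, with 40 below 0 (camera adjusted p = 1.22e-06, and adjusted p = 0.981 with an estimated correlation), and medians of -0.193, -0.294 and -0.306 in the 3 loops. The median lay between -0.359 and -0.189 under 8 other scans, background corrections and scalings. Of these genes Rpl13a and Rpl22l1 were lower (-1.03 and -0.921), Rpl3, above background in 2 of 6 channels at day 2, was higher (1.03) and the others did not pass. The 36 Rps genes, which by prefix include a few S6 kinases, had a median of -0.212 with 31 below 0 (camera adjusted p = 0.000838, and adjusted p = 0.981 with an estimated correlation). Of the 36, 1 was called lower. Of 17 keratin genes, 6 were called lower at day 2, and these were in the fixed lists apart from Krt20. The other keratin genes did not pass, and 14 of the 17 had a change below 0 (median -0.618, camera adjusted p = 0.000732, and adjusted p = 0.981 with an estimated correlation). Under those 8 settings their median stayed between -0.637 and -0.37. All 8 called Ugt genes at day 2 belonged to the Ugt1a cluster, whose members share their last exons, so that their near-equal rises of 1.17 to 1.47 cannot be counted as 8 separate changes, and a dimmer second probe of Ugt1a1 gave 0.0729.

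Control spots for genes often used as references moved as well. The actin gene Actb changed by -1.04 ± 0.16 at day 2 and -1.51 ± 0.17 at day 7, and Gapdh by -1.19 ± 0.11 and -1.37 ± 0.19 (SD, n = 3). Both stayed negative under 6 other scans, background corrections and scalings. The values of Hprt were 0.00 ± 0.12 and 0.18 ± 0.01 (SD, n = 3), and those of Tbp 0.16 ± 0.18 and 0.25 ± 0.17 (SD, n = 3). At day 2 the sign of Hprt turned among those settings, from -0.0509 to 0.0863.

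The calls between day 7 and day 2 were one-sided, with 808 of 907 higher at day 7. Scaling that produced this could bring the share of higher calls near balance under another setting, but it lay between 84.49% and 90.57% under 8 alternatives. Each of the 8 left the median change of all genes between -0.00717 and 0.0152, so none could balance the calls by moving the centre. If signals near background caused it, probes above background in all 18 channels would be balanced, but 82.97% of those 364 calls were higher. Of the 808 higher calls, 506 were not above background in all 18 channels. The share of higher calls was 89.08% in the main fit, 79.72% with a stricter filter on dim probes and 81.48% with the random-sequence filter. Outside the 8 alternatives it lay between 76.87% (array weights) and 97.28% (separate channels, no replicate block). These values argue against signals near background as the sole cause, while a contribution of dim signals stays open. For scaling they show only that the share held under the 8 settings tried, which does not decide the cause. The centre of the log ratios was not varied by any of the 8, and a shift of all changes by 0.19 would bring the share to at most 60%, so that centring stays open and no biological reading is drawn.

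Dcn and Lyz2, which are known from fibroblasts and macrophages, rose on both days. Fibroblasts would bring their collagens, and the other 5 fibroblast genes had a median change of -0.248 at day 2 and none was called higher. Macrophages would bring their other transcripts, and the other 7 immune genes had a median of 0.0604 with a standard error of 0.218, and Cd68 fell. In both lists most of these genes were near background at day 0 or day 2, so that fibroblasts and macrophages stay open. The fall of Cd68, a single gene, does not decide on macrophages. Epithelial expression of these 2 genes may account for their rise and was not tested, and for Lyz2 the near-identical Lyz1 keeps the identity of the transcript open.

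Another hypothesis was that the fall of hypoxia and glycolysis genes follows the fall of cell division. From day 2 to day 7 the proliferation list fell further, with medians of -0.578, -0.683 and -0.514 in the 3 loops, and the hypoxia and glycolysis medians were -0.0927, -0.0987 and -0.0417. The smallest gap between the lists in a loop was 0.473, which restates medians seen before, and a dependence on cell division that ends at a floor stays open. Exposure to air is a candidate explanation of the fall by day 2. From day 2 to day 7 the list's median change was -0.00684, but its mean was -0.117 and fry called it lower (adjusted p = 0.0128), so the fall may have gone on. Exposure to air cannot be told apart from time in culture or a change of medium, because these go with the day.

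Of 36 labellings of the days within loops, the real one gave 3285 genes changed across the 3 days and the others at most 885. A share of 1 in 36 is the smallest this relabelling can give, so chance is unlikely for that count but not excluded. For the pairs of days the 4 sign patterns of 3 loops are too few for a share under 0.05. The real counts were 1509, 3878 and 907, and the highest other count was 0 in each.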
